A study of Mus musculus with 12 samples.

How the data were processed

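RNA was measured in L4 to L6 dorsal root ganglia (DRG, the ganglia that hold the cell bodies of sensory neurons) of C57BL/6 mice aged 6 to 8 weeks. Each of the 12 libraries came from the pooled DRG of 2 mice, and each of the 4 groups had 3 libraries. Mice received indole-3-propionic acid (IPA, an indole that gut bacteria make from tryptophan) at 20 mg/kg or phosphate-buffered saline as vehicle, by daily gavage for 10 days. DRG were taken without injury, or 3 days after a crush of the sciatic nerve. Per the labels' protocols, IPA gavage went on for those 3 days; whether vehicle gavage also went on is not clear from the labels. The labels give neither sex nor batch. Poly(A) RNA with an integrity number above 8.0 was made into directional libraries and read as pairs of 75 bases on an Illumina HiSeq4000, per the labels' protocols.

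The submitters' processing notes name the mouse build mm10, STAR 2.7.0, edgeR 3.24.3, limma 3.38.3, R 3.5.0 and FastQC 0.10.1, with no role or order; the read counter and the annotation are not given in the sources used here. The authors deposited 1 table of 44345 genes whose name says FPKM, but its values behave as CPM-like values in which no gene length was divided out. In each library 100.0% of the values were whole multiples of 1 step shared by all genes, within a tolerance of 1e-06, so the reads behind each value could be recovered. The columns sum to between 803444 and 818767. Read as FPKM, the divisors of all 12 libraries shared a factor of 1038, whose origin is not known. With that factor taken out, the divisor was 1.18 to 1.20 times the recovered reads. The recovered reads came to 40938034 to 62501969 per library, and 1 read was worth 0.0130 to 0.0199 of the deposited unit. The 10 highest genes took 3.73% to 4.28% of the summed values. Of the listed IDs, 38253 were Ensembl IDs, 36588 of which are in GENCODE M21, and 6083 were UCSC IDs that held 0.167% of the summed value; 15112 genes were at 0 in every library. Gene coordinates are on mm10 (GRCm38), from GENCODE M21. No replicate pair agreed within sampling noise: chi-square per degree of freedom was 4.55 to 26.3.

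The design fixed before the data were examined assumed FPKM, and its test was kept, since it suits both units. That design named edgeR (quasi-likelihood) in place of limma if the file held counts. The file held scaled values, and running edgeR beside limma on recovered reads was decided after the data were seen. The values were taken as log2(value + 0.5), genes with at least 0.5 in at least 3 of the 12 libraries were kept (15603), and all libraries were fitted in 1 limma-trend model (limma 3.58.1 in R 4.3.3) with 8 residual degrees of freedom. A fold change on this scale understates the change of low genes. The 6 contrasts were injury under vehicle, injury under IPA, IPA without injury, IPA after injury, the interaction, and IPA averaged over both injury states. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Lists of genes, 26 in all and fixed before the data were examined, cover neuron classes, glia, immune cells, neighbouring tissues and metabolic pathways. They were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists within a contrast, and again with an estimated correlation and with fry. Older symbols in the lists were matched through Ensembl IDs.

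The genes named were set by a rule fixed before the data were examined: the 10 largest rises and falls among genes that passed, with a mean of at least 1 and no overlap between groups; up to 4 members per list with the smallest p, or 2 members given as values where only the list was called; a fixed set of injury, neutrophil and receptor-target genes; and, with fewer than 5 genes passing, the 6 genes with the smallest p. Replicates are separate pools of mice, per the labels.

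The alternatives fixed beforehand were pseudocounts of 0.1 and 1, no filter, a filter of 1, median-of-ratios scaling, quantile normalization, the replicate number as a block, array weights, robust empirical Bayes, a threshold of 0.1, only the 6 libraries compared, and each library left out in turn. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, other forms of the array weights, and removal of each library's trend on transcript GC content and length (longest GENCODE M21 transcript, known for 97.9% of the tested genes). The model was tested on simulated counts with 200 changed genes among 15603, 50 at each fold. It recovered 86% of genes changed 1.5-fold in the contrast of IPA without injury, 82% in IPA after injury, 96% in the averaged contrast and 70% in the interaction. At 1.25-fold the shares were 38%, 42%, 80% and 12%. The changed genes were drawn only from those with a mean of at least 1, so lower genes are not covered. The simulation draws each gene on its own and holds no trend shared by the genes of a library. These shares hold for that setting only.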

Results

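Gene expression was measured in sciatic DRG of mice given IPA or vehicle, with the sciatic nerve intact or 3 days after a crush. The 4 groups were vehicle, IPA, vehicle with injury and IPA with injury, each with 3 libraries of 2 pooled mice. Recovered reads ranged from 41694916 to 49481144 in vehicle, 51482387 to 56798355 in IPA, 40938034 to 58013747 in injured vehicle and 44808587 to 62501969 in injured IPA libraries. Values below are the deposited CPM-like values as mean ± SD over 3 libraries, and log2 fold changes carry their standard error (SE) from the limma model. The first principal component of the 15603 tested genes held 76.4% of the variance and separated injured from uninjured libraries; the others held 8.37% or less. On the second, the uninjured IPA libraries scored 5.49 to 11.8 and the uninjured vehicle libraries -12.5 to 1.28, while injured IPA libraries scored 1.31 to 6.54 and injured vehicle libraries 5.04, 1.29 and, in replicate 1 alone, -23.6. That library also differed most from its replicates (chi-square per degree of freedom 26.3 and 24.1, against 5.38 between the other two). Among uninjured libraries, the order on the second component was also that of their slopes on transcript GC content, from -0.091 to 0.041. On the next, injured IPA replicate 3 (16.3) and replicate 1 (-12.7) of the same group lay at opposite ends.

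**Figure D1:**
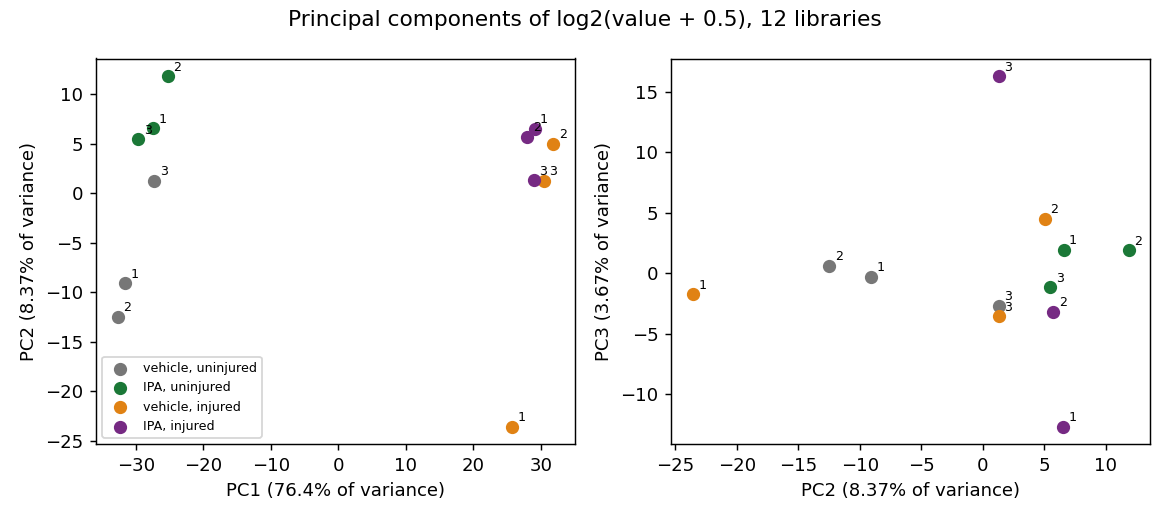
Scores of the 12 libraries on the first 3 principal components of log2(value + 0.5), coloured by group and numbered by replicate. The first component, with 76.4% of the variance, separates injured from uninjured libraries, and the second parts uninjured IPA from uninjured vehicle libraries but not the injured ones. Among uninjured libraries, the order on the second is also that of their slopes on transcript GC content.

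The first comparison asked what nerve injury changed in DRG of vehicle-treated mice. Sprr1a, a gene induced in injured sensory neurons (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895), rose from 1.83 ± 0.80 to 642.5 ± 49.6, a log2 change of 8.17 ± 0.19. The neuropeptides Npy and Gal rose by 6.33 ± 0.18 and 5.02 ± 0.10 on the log2 scale. Atf3, a transcription factor of the injury response (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039), rose from 11.2 ± 1.03 to 517.6 ± 7.40, and the receptor Gpr151 from 1.16 ± 0.28 to 115.1 ± 0.71. Other large rises were in Slc6a4 (the serotonin transporter, 5.38 ± 0.12), Ecel1 (5.31 ± 0.17), Cckbr (5.25 ± 0.16), Fgf3 (4.86 ± 0.12) and Lipn (4.86 ± 0.10). The growth-associated genes Sox11, Gap43 and Jun rose by 2.64 ± 0.12, 1.82 ± 0.07 and 1.36 ± 0.09. The largest falls were smaller: the delta opioid receptor gene Oprd1 fell from 18.7 ± 2.76 to 4.90 ± 0.82, a log2 change of -1.83 ± 0.13. Dnahc6 changed by -1.63 ± 0.19, Comp by -1.55 ± 0.12, Lingo4 by -1.54 ± 0.22, Chrnb3 by -1.52 ± 0.12, Kcna2 by -1.48 ± 0.19 and Chrna6 by -1.45 ± 0.07. In all, 3683 genes rose and 3801 fell (limma, adjusted p under 0.05), with 529 rises and 104 falls over 2-fold; the remaining calls were of smaller size.

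Neuronal lists moved in opposite directions after injury. Of 46 regeneration-associated genes, 44 rose and 1 fell (camera adjusted p = 7.46e-35, and adjusted p = 0.00161 with an estimated correlation), Fst by 3.86 ± 0.08. Of 26 genes of large-diameter neurons, 25 fell and 1 rose (adjusted p = 4.24e-11, and adjusted p = 0.0190 with an estimated correlation), among them the transcription factor Etv1 at -1.07 ± 0.07 and the potassium channel Kcna1 at -0.56 ± 0.05. Of 35 nociceptor and small-diameter neuron genes, 29 fell and 5 rose (adjusted p = 1.98e-08, but adjusted p = 0.268 with an estimated correlation). The serotonin receptor subunit Htr3a changed from 159.1 ± 8.66 to 65.6 ± 5.60, while Gfra3 rose by 0.90 ± 0.06. Counts adjusted over the list alone were identical for these 3 lists.

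Macrophage, chemotaxis and interferon lists were higher after injury. All 28 measured macrophage markers rose (adjusted p = 1.62e-13, adjusted p = 0.268 with an estimated correlation), including the mannose receptor Mrc1 at 1.80 ± 0.11 and the fractalkine receptor Cx3cr1 at 1.59 ± 0.12. Of 39 neutrophil and monocyte chemotaxis genes, 25 rose and 1 fell (adjusted p = 2.49e-07, adjusted p = 0.435 with an estimated correlation), with Lgals3 at 1.99 ± 0.06, Ccl9 at 1.67 ± 0.12 and Il1r1 at 1.08 ± 0.08. Of 37 type I interferon response genes, 20 rose and 1 fell (adjusted p = 0.000367, adjusted p = 0.787 with an estimated correlation), with Ifi44 at 1.29 ± 0.19. Of 22 proliferation genes 16 rose (adjusted p = 4.33e-05, adjusted p = 0.54 with an estimated correlation), Prc1 by 2.31 ± 0.08. Of 40 cytosolic ribosomal protein genes 37 rose (adjusted p = 1.21e-11, adjusted p = 0.268 with an estimated correlation), Rps3 by 0.61 ± 0.05. Of 22 fibroblast and meningeal genes 8 rose (adjusted p = 0.0255, adjusted p = 0.787 with an estimated correlation), Lum by 0.51 ± 0.11. Skeletal muscle markers differed as well: 3 of 22 rose (adjusted p = 0.0255, adjusted p = 0.806 with an estimated correlation), none of them when adjusted over the list alone. The fibroblast call was lost without vehicle replicate 1 (adjusted p = 0.0596) or injured vehicle replicate 3 (0.0584), and the muscle call without vehicle replicate 2 (0.0596), injured vehicle replicate 1 (0.178) or injured vehicle replicate 3 (0.0584).

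The other 16 lists were not called by camera under vehicle. Of these, fry, which does not compare a list with other genes, called 7: mature neutrophil, precursor granule, receptor-target, clock (although with a median of -0.08), cholesterol and immediate early genes higher and bone and cartilage genes lower. Among mature neutrophil markers 5 of 21 rose and 1 fell (camera adjusted p = 0.0674, fry 0.0259), Ly6g from 0.146 ± 0.012 to 1.76 ± 0.29. Of 11 neutrophil precursor granule genes (camera adjusted p = 0.0668, fry 0.00332) the 2 that rose, Serpinb1a at 2.39 ± 0.09 and Anxa1 at 2.92 ± 0.12, are not specific to neutrophils. Of 11 targets of the aryl hydrocarbon and pregnane X receptors 4 rose and 1 fell, Abcc3 by 0.78 ± 0.12. Satellite glia genes went both ways (3 higher, 4 lower of 20), with Glul, glutamine synthetase, at 0.84 ± 0.07 and Kcnj3 at -0.89 ± 0.09. Of 17 circadian clock genes 5 rose and 6 fell, of 23 cholesterol synthesis genes 8 rose and 3 fell, of 16 immediate early genes 7 rose and 3 fell, and of 33 respiratory chain genes 2 rose and 7 fell. With the GC and length trend of each library removed, the respiratory chain list was called lower (median -0.15 against -0.01, adjusted p = 0.00316), and the ribosomal median was 0.19 against 0.35. In the remaining lists, members passed among myelinating Schwann cell genes (3 higher, 1 lower of 20), lymphoid markers (1 and 2 of 10), adipocyte genes (4 and 1 of 12), endothelial and pericyte genes (4 and 2 of 20), central glia genes (1 and 3 of 9), bone and cartilage genes (0 and 3 of 9), erythroid genes (1 and 0 of 13) and MHC class II genes (0 and 0 of 7).

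The injury effect under IPA asked whether treated mice showed the same changes. Injured IPA mice were gavaged for 3 more days than uninjured IPA mice, so this contrast mixes injury with the length of dosing. Sprr1a rose by 7.87 ± 0.19, Npy by 6.11 ± 0.18, Gpr151 by 5.95 ± 0.11, Atf3 by 5.36 ± 0.05 and Gal by 5.08 ± 0.10 on the log2 scale. Sox11 rose by 2.69 ± 0.12, Gap43 by 1.75 ± 0.07 and Jun by 1.41 ± 0.09. Oprd1 changed by -1.56 ± 0.13, Glb1l2 by -1.39 ± 0.10, Comp by -1.36 ± 0.12 and Insrr, a receptor related to the insulin receptor, by -1.35 ± 0.10. In total 3303 genes rose and 3505 fell (limma, adjusted p under 0.05), 463 and 76 of them over 2-fold. The regeneration-associated list (44 of 46 higher, adjusted p = 0.00118 with an estimated correlation) and the large-diameter list (25 of 26 lower, adjusted p = 0.0143 with an estimated correlation) passed again. Nociceptor genes (5 higher, 27 lower of 35, adjusted p = 0.356 with an estimated correlation) were called lower by camera. Macrophage (26 of 28 higher, 0.320), chemotaxis (24 higher, 1 lower of 39, 0.356), interferon (16 higher, 2 lower of 37, 0.765), proliferation (17 of 22 higher, 0.356) and ribosomal protein genes (35 of 40 higher, 0.320) were called higher, each with its adjusted p at an estimated correlation in brackets. The interferon median was 0.38, and 0.21 without IPA replicate 3 or 0.23 without injured IPA replicate 3. Of the lists that camera called, fry did not call interferon (adjusted p = 0.0581) or muscle genes (0.205). Fibroblast and meningeal genes, called higher under vehicle, were not called under IPA (4 higher, 3 lower of 22, median -0.12, adjusted p = 0.812). Muscle genes were called higher (2 of 22, none adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.834 with an estimated correlation). Their median was 0.87, and 0.41 to 1.36 over the fits with 1 library left out. The call was lost without IPA replicate 1 (median 0.77, adjusted p = 0.0699) or injured IPA replicate 1 (median 0.41, adjusted p = 0.291). Mature neutrophil markers, close to the threshold under vehicle, were called by camera under IPA, with 13 of 21 higher (camera adjusted p = 0.00182, adjusted p = 0.659 with an estimated correlation), and so were precursor granule genes, with 4 of 11 higher and 1 lower (adjusted p = 0.00672, adjusted p = 0.659 with an estimated correlation). Lcn2 rose by 1.28 ± 0.42 and Prtn3 by 0.79 ± 0.29, and both had their highest value in injured IPA replicate 3. Without that library neither passed (0.78, adjusted p = 0.117, and 0.54, adjusted p = 0.174), and the median change fell from 0.78 to 0.43 for mature neutrophil markers and from 1.04 to 0.65 for precursor granule genes, with both lists still called. With the GC and length trend removed, respiratory chain genes were called lower here too (median -0.16, adjusted p = 0.000863).

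Most called genes were shared by both treatments. Of these, 2975 rose in both, where independent lists would share 780, 3030 fell in both, where they would share 854, and 0 went opposite ways. Across genes, which are not independent replicates, the fold changes correlated at r = 0.961 (Spearman's rho = 0.913), and the slope of the IPA on the vehicle changes was 0.905. The 2 contrasts share no library. Injured IPA mice also had 3 more days of dosing, so differences between the contrasts cannot be ascribed to injury alone. Of 1479 genes called only under vehicle 1420 had the same sign under IPA, and of 803 called only under IPA 769 had the same sign under vehicle. No gene passed the test of the difference with limma or edgeR, and DESeq2 called 3.

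**Figure D2:**
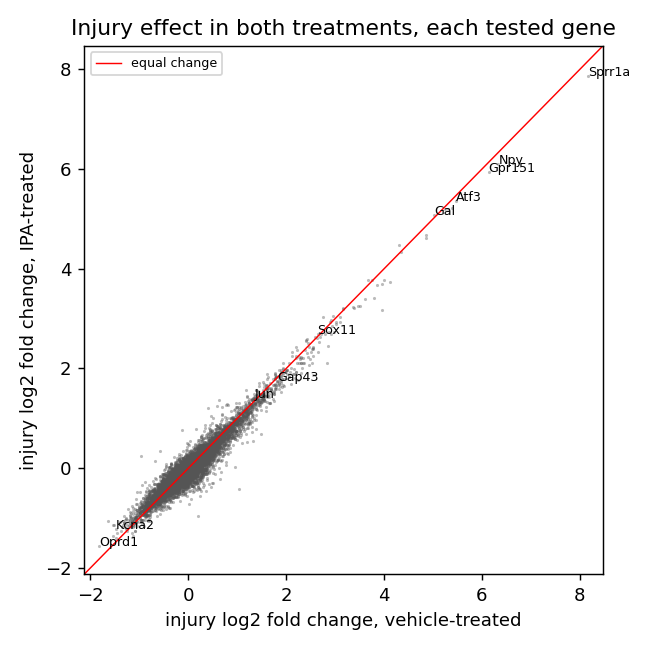
Log2 fold change after injury for each of the 15603 tested genes, vehicle-treated mice on the x axis and IPA-treated mice on the y axis, with the line of equal change. Regeneration genes such as Sprr1a and Atf3 lie at the upper right in both treatments, and the changes correlate at r = 0.961 across genes.

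IPA without injury was compared with vehicle to ask what IPA alone changed. No gene passed with limma (0 of 15603; smallest adjusted p = 0.400; 1902 genes at an unadjusted p under 0.05 where 780 would be given by chance) or edgeR, and DESeq2 called 3. The lowest p values belonged to Mmp16, a membrane metalloproteinase (6.98 ± 0.88 under vehicle, 4.80 ± 0.33 under IPA), Adam8 (5.25 ± 1.03 and 8.66 ± 0.60), Fam167a (15.3 ± 0.55 and 12.2 ± 0.37), the orexin receptor gene Hcrtr1 (4.03 ± 0.31 and 5.52 ± 0.19), Emp3 (14.8 ± 0.28 and 17.6 ± 0.75) and Capn11 (1.93 ± 1.21 and 0.189 ± 0.029). Camera called 3 lists with no member past the test: ribosomal protein genes higher (median log2 change 0.11, adjusted p = 7.66e-07), interferon response genes higher (0.21, adjusted p = 0.000661) and skeletal muscle genes lower (-0.55, adjusted p = 0.000661). Each had adjusted p = 0.859 with an estimated correlation. Mean log2 levels in IPA replicates 1, 2 and 3 were 3.02, 3.15 and 2.63 for interferon, 2.13, 2.20 and 1.80 for macrophage, 1.254, 1.307 and 0.963 for chemotaxis and 3.82, 4.32 and 3.62 for MHC class II genes; the last 3 lists were not called (adjusted p = 0.144, 0.225 and 0.204). The interferon call was lost without IPA replicate 2 (median 0.10, adjusted p = 0.0854) and the muscle call without IPA replicate 1 (-0.34, adjusted p = 0.0738), and the ribosomal median was 0.06 without vehicle replicate 2 and 0.04 with the GC and length trend removed. That removal left the 3 calls and added 7, given here by median and camera adjusted p. Nociceptor (-0.05, 0.0194), large-diameter neuron (-0.04, 0.00793) and erythroid genes (-0.14, 0.0295) were lower. Chemotaxis (0.09, 0.0252), macrophage (0.08, 0.0320), adipocyte (0.18, 0.0252) and fibroblast genes (0.07, 0.0295) were higher. An estimated correlation was not run on these corrected values. Cyp1b1, a target of the aryl hydrocarbon receptor, was 34.7 ± 1.43 and 31.8 ± 2.12. Ahrr was 2.72 ± 0.32 and 2.45 ± 0.17, and Cyp1a1 and Nr1i2 were below the filter. The 95% interval lay within 1.5-fold for 14816 genes.

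IPA after injury asked the same in the crushed-nerve groups. There IPA gavage went on for the 3 days after the crush, and whether vehicle gavage did is not clear. No gene passed with limma (0 of 15603; smallest adjusted p = 0.364; 1258 genes at an unadjusted p under 0.05) or edgeR, and DESeq2 called 12. The lowest p values belonged to Ndn, the imprinted gene necdin (152.8 ± 4.50 under vehicle, 205.6 ± 21.6 under IPA), Gpr162 (17.7 ± 0.66 and 22.7 ± 0.44), Bhlha9 (5.76 ± 0.19 and 8.18 ± 0.96), Th, tyrosine hydroxylase (51.1 ± 4.24 and 65.3 ± 3.12), C1ql4 (3.88 ± 0.07 and 5.85 ± 0.65) and Hcrtr1 (4.01 ± 0.37 and 5.75 ± 0.54). The neutrophil gene S100a8 was 9.12 ± 3.69 under vehicle and 14.02 ± 11.2 under IPA, S100a9 was 15.7 ± 5.39 and 20.8 ± 14.6, Ly6g was 1.76 ± 0.29 and 1.64 ± 0.39, Cxcr2 was 0.625 ± 0.235 and 0.806 ± 0.373, and Csf3r was 1.80 ± 0.36 and 1.96 ± 0.71. Injured IPA replicate 3 held 26.9 of S100a8 and 37.2 of S100a9; without it the IPA means were 7.58 and 12.6, below those of vehicle, and those of Cxcr2 (0.590) and Csf3r (1.56) were below vehicle too. Cxcl1 and Cxcl2 were below the filter and were not tested. With 1 read worth 0.0130 to 0.0199, Cxcl1 was 0.063 ± 0.040 under vehicle and 0.184 ± 0.042 under IPA. Cxcl2 was 0.019 ± 0.018 and 0.022 ± 0.038. Cyp1b1 was 99.5 ± 6.61 under vehicle and 89.8 ± 1.90 under IPA (limma adjusted p = 0.602). Ahrr was 1.79 ± 0.23 and 1.63 ± 0.21. The receptor-target list was not called (camera adjusted p = 0.268), with 4 of 11 members above 0. Camera called 8 lists with no member past the test: fibroblast and meningeal genes lower (median log2 change -0.14, Fmod 5.99 ± 1.04 and 4.05 ± 0.46), muscle genes lower (-0.59), erythroid genes lower (-0.20), large-diameter neuron genes lower (-0.05), and ribosomal protein (0.06), interferon response (0.14), immediate early (0.11) and nociceptor genes (0.02) higher. All 8 had adjusted p = 0.822 with an estimated correlation. Without injured IPA replicate 3, 4 calls were lost: muscle (median -0.08, adjusted p = 0.987), interferon (0.04, adjusted p = 0.729), large-diameter neuron (-0.07, adjusted p = 0.729) and ribosomal protein genes (0.06, adjusted p = 0.0937). Each of the other lists except the fibroblast list lost its call without at least 1 other library: nociceptor genes without 4 of the 6 in turn (highest adjusted p = 0.643 without injured vehicle replicate 2; the median turned to -0.01 without injured vehicle replicate 3 and was 0.11 without injured vehicle replicate 1), immediate early genes without 3 (median 0.03, adjusted p = 0.187 without injured IPA replicate 1) and erythroid genes without 2 (median -0.115, adjusted p = 0.253 without injured vehicle replicate 2, and median -0.118, adjusted p = 0.165 without injured IPA replicate 2; the median was -0.34 without injured IPA replicate 3). Interferon and large-diameter calls were also lost without injured vehicle replicate 3 (adjusted p = 0.276 and 0.261), the latter also without injured vehicle replicate 1 (0.0659). The fibroblast median was -0.07 without injured IPA replicate 1. Over the fits with 1 library left out, the muscle median ran from -1.12 to -0.08. With the GC and length trend removed, immediate early genes were not called (adjusted p = 0.0770), and the medians were 0.03 for ribosomal protein and 0.05 for nociceptor genes.

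The interaction asked whether the IPA effect differed between injured and uninjured DRG. Injured IPA mice were also gavaged for 3 more days, so injury cannot be told apart from the length of dosing here. No gene passed with limma (0 of 15603; smallest adjusted p = 0.639, 327 genes at an unadjusted p under 0.05) or edgeR, and DESeq2 called 3. The lowest p belonged to the matrix gene Mfap4, with an interaction of -1.17 ± 0.20, followed by Fn1, fibronectin, at -0.73 ± 0.16 and Adam8 at -0.78 ± 0.17. Camera called fibroblast and meningeal, adipocyte, macrophage and chemotaxis genes lower and nociceptor and mature neutrophil markers higher in the interaction. Their adjusted p was 0.772 to 0.999 with an estimated correlation. Mature neutrophil markers had a median interaction of 0.27, which was 0.03 without injured IPA replicate 3 (adjusted p = 0.568), the library with the highest S100a8. With each of the 12 libraries left out in turn, the fibroblast and nociceptor calls were kept, while the neutrophil call was lost in 6 cases, chemotaxis in 7 (highest adjusted p = 0.565 without vehicle replicate 2), macrophage in 7 (0.267 without injured IPA replicate 1) and adipocyte in 4 (0.725 without injured IPA replicate 1). Over these fits the median interaction was -0.43 to -0.23 for fibroblast, 0.05 to 0.17 for nociceptor, 0.03 to 0.40 for neutrophil, -0.19 to -0.04 for chemotaxis, -0.23 to -0.01 for macrophage and -0.42 to -0.02 for adipocyte genes.

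Averaged over both injury states, 0 genes passed with limma (smallest adjusted p = 0.122) or edgeR and 358 with DESeq2, and 3153 had an unadjusted p under 0.05 with limma against 780 by chance. Hcrtr1 had a log2 difference of 0.44 ± 0.06, Bhlha9 of 0.39 ± 0.06, Gpr162 of 0.27 ± 0.04, Mmp16 of -0.36 ± 0.06, Ppm1j of 0.20 ± 0.04 and Rnf112 of 0.22 ± 0.04, each with n = 6 libraries per treatment. Ribosomal protein genes had a median of 0.08 (33 of 40 above 0), interferon genes of 0.17 (36 of 37 above 0) and muscle genes of -0.57 (22 of 22 below 0); these, erythroid, immediate early and respiratory chain genes were called by camera and had adjusted p = 0.965 with an estimated correlation. Without injured IPA replicate 3 the muscle median was -0.27 (adjusted p = 0.0621). With each of the 12 libraries left out in turn, the ribosomal and interferon calls were kept, the interferon median being 0.11 without IPA replicate 2 and 0.12 (adjusted p = 0.0435) without injured IPA replicate 3, while erythroid and immediate early genes lost theirs in 4 cases each (highest adjusted p = 0.109 without injured vehicle replicate 2 and 0.140 without injured IPA replicate 1) and respiratory chain genes in 7 (0.187 without injured IPA replicate 3). The IPA effects in the 2 injury states, which share no library, correlated across genes at r = 0.487 (rho = 0.511), with 70.1% of genes of the same sign. The log2 differences also followed transcript GC content (r = 0.53 across genes) and length (r = -0.311). After that trend was removed, immediate early and respiratory chain genes were no longer called (adjusted p = 0.366 for both), large-diameter neuron genes were called lower (median -0.04, adjusted p = 0.000262), and the ribosomal median was 0.04.

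The count of 0 for IPA depended on the tool, as the DESeq2 counts on the recovered reads show. The 358 averaged DESeq2 calls came from 8889 genes left by its own filter, against 17924 tested by edgeR. DESeq2 was not refitted on other groupings of the libraries, so its counts have no chance count beside them. Weights estimated for each library, an alternative fixed beforehand, gave 4160 genes without injury, 4000 after injury, 2126 in the interaction and 5259 averaged, from an estimate that did not converge and that gave injured IPA replicate 2 a weight of 42.2. Weights estimated gene by gene, chosen after seeing the data, converged and gave 3273, 324, 2 and 3135. With the prior of the weights set at 100 in place of 10, they converged too and gave 2916, 75, 2 and 2610. At that prior the form fixed beforehand, again without converging, gave 3825, 22, 2 and 2905.

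**Figure D3:**
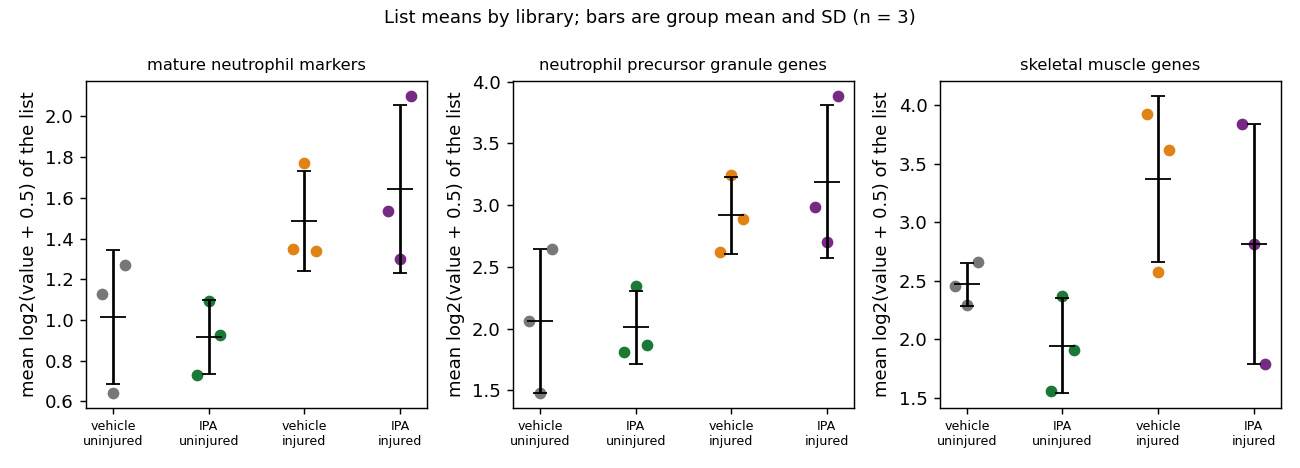
Mean log2(value + 0.5) over the members of 3 gene lists in each of the 12 libraries, by group, with points for libraries and bars for the group mean and SD (n = 3). Injured IPA replicate 3 has the highest neutrophil means of the injured IPA group, and the lowest muscle mean.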

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

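The tests of the GC slope, of bone marrow, of the neutrophil list mean, both muscle tests and the splits at an unadjusted p were chosen only after the result was seen. A test of the difference between injury states, the interaction, singled out 6 gene lists by camera: fibroblast and meningeal genes (adjusted p = 1.25e-10), nociceptor and small-diameter neuron genes (8.01e-05), mature neutrophil markers (0.00971), macrophage markers (0.00971), adipocyte genes (0.0160) and neutrophil and monocyte chemotaxis genes (0.0463). None was called with an estimated correlation (smallest adjusted p = 0.772) or by fry (0.993). No single gene passed with limma or edgeR, and DESeq2 called 3.

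GC-rich and short genes were on average higher in IPA libraries. Without injury the slopes on GC content were 0.013, 0.041 and 0.003 under IPA and -0.065, -0.091 and -0.003 under vehicle. After injury they were 0.086, 0.054 and -0.018 under IPA and -0.097, 0.044 and 0.034 under vehicle. The injured difference in this slope thus rested on injured vehicle replicate 1. With every library thinned to the shallowest, 3110 genes had an unadjusted limma p under 0.05 in the averaged contrast, against 3153 before. Whether these were the same genes was not counted. Thinning keeps the expected share of each gene, so this argues only against the number of reads counted. It cannot test a bias that came with depth. Without injury each IPA library held more recovered reads than each vehicle library. With each library's trend on GC content and length removed, the count was 2245, above 1.5 times chance but under 80% of the original count. The median SE also fell, from 0.0593 to 0.0479, so the counts before and after are not on a like footing. That trend may account for part of the difference, and the test leaves it open. The slope on GC content was higher under IPA by 0.0597 on average (two-sided exact permutation p = 0.07 within injury states), so an effect of IPA stays open too.

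Neutrophil granule genes were highest in injured IPA replicate 3. The interaction of the mature neutrophil list mean was 0.26 on the log2 scale (two-sided exact permutation p = 0.455 within injury states), which leaves an effect of IPA open. Against the other injured IPA libraries, replicate 3 was higher by a median log2 difference of 1.18 ± 0.25 (SE over members) in precursor granule genes, 0.49 ± 0.08 in erythroid genes, 0.37 ± 0.04 in interferon, 0.31 ± 0.05 in chemotaxis, 0.30 ± 0.06 in proliferation and 0.24 ± 0.05 in macrophage genes, and it differed by -1.56 ± 0.11 in muscle genes and 0.01 ± 0.10 in T, B and NK cell markers. Members of a list move together and a single library is compared, so these SEs do not measure the spread between samples. The proliferation value lies on the bound set for bone marrow, so marrow in that sample is a candidate source that cannot be told apart from a wider difference in the makeup of the tissue.

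Skeletal muscle genes had a lower mean in IPA libraries, which after injury rested on replicate 3 (median -0.59, and -0.08 with adjusted p = 0.987 without it). Over the injured fits with 1 library left out, the median went as low as -1.12. Without injury the call was lost without IPA replicate 1 (adjusted p = 0.0738). Their deviations from the group means moved together, with a median pairwise correlation of 0.921, consistent with varying amounts of muscle tissue in the samples. The difference of the list mean, -0.54 on the log2 scale, had an exact permutation p of 0.16 within injury states (two-sided), so an effect of IPA on muscle genes stays open.

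Other groupings of the libraries were refitted. For injury, the 10 splits of 6 libraries are too few for a share under 0.05; the real count under vehicle was 7484 and the highest other 51, and under IPA 6808 and 0. With a real count of 0 any split gives as many, so the splits decide nothing for IPA without and after injury (10 of 10 in each, the highest other 1 and 28), the interaction or the averaged contrast (100 of 100 drawn in each, the highest other 10 and 21). At an unadjusted p under 0.05, 6 of 100 splits gave as many genes as the real averaged contrast (3153, the highest other 4885), so chance cannot be excluded. With gene-by-gene library weights, a fit chosen after seeing the data, 3 of 100 splits reached the real averaged count of 3135, but the highest other gave 3822 and 27 of the other 99 called genes. After injury 2 of 10 splits, the real one included, reached the real 324, and the highest other gave 460. Without injury the real count was 3273 and the highest other 3050, again with too few splits for a share under 0.05. Whether these calls come from the samples or from weights estimated anew in each split was not tested.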

How the results depend on the processing

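Among named genes, 3964 of 4098 alternative values were counted as unchanged, 80 lost the call, 2 gained one and 52 moved. Where neither fit called the gene, unchanged means a shift within the SE, whatever the side. A reversal was counted only where a fit called the gene, and there were 0. Changes of side among uncalled genes were not counted. Among called lists, 550 of 688 kept the call, 138 lost it and 0 reversed. edgeR, DESeq2, the GC and length correction, other weight forms and the GC-corrected lists were chosen after seeing the data. The injury counts stayed within 1.5 times under every alternative run, except that library weights gave 11150 under IPA. The IPA counts of 0 became 4160 without injury, 4000 after injury, 2126 in the interaction and 5259 averaged with library weights, whose estimate did not converge, and 3273, 324, 2 and 3135 with converged gene-by-gene weights; injured vehicle replicate 1 had the lowest weight (0.146 and 0.185). DESeq2 gave 3, 12, 3 and 358. With the prior of the weights at 100 in place of 10, converged gene-by-gene weights gave 2916, 75, 2 and 2610. The form that did not converge gave 3825, 22, 2 and 2905 at that prior. Leaving out 1 library gave 0 to 1 gene after injury (Ndn without injured IPA replicate 2, Isl2 without injured IPA replicate 3) and 0 to 3 genes averaged (Mvb12a, Isl2 and Bhlha9 without injured IPA replicate 3); these were named after their values were seen. Lists called fell with an estimated correlation from 10 to 2 for injury under vehicle, from 11 to 2 under IPA, and to 0 in the 4 IPA contrasts. By fry, 16 were called for injury under vehicle, 14 for injury under IPA and 0 in the 4 IPA contrasts. GC and length correction raised the lists called for IPA without injury from 3 to 10. Leaving out 1 library gave 2 to 8 lists for IPA without injury, 4 to 9 after injury, 2 to 9 in the interaction and 3 to 8 averaged. The correlation of the IPA effects, 0.487, was 0.428 with a pseudocount of 0.1 and 0.331 after GC and length correction. The replicate numbers did not pair the libraries: 4 of 18 same-number pairs correlated above 0.1 (range -0.252 to 0.286), and 3 of 12 libraries correlated best with their own number. With the number as a block 7210 and 6515 genes passed for injury, and 0 in each IPA contrast. The cause of these changes was not tested. At the lowest fold simulated, 12% of changed genes were recovered in the interaction, which limits what could be detected there.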

Other observations

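The matrix genes Mfap4 and Fn1 and the gene Adam8 had the lowest p values for a different IPA effect between injury states, although none passed with limma. Mfap4, a protein of elastic fibres, was 1.39 ± 0.24 under vehicle and 2.22 ± 0.25 under IPA without injury, and 1.69 ± 0.41 and 0.89 ± 0.12 after injury. Fn1, fibronectin, was 29.3 ± 2.96 under vehicle and 34.6 ± 6.71 under IPA without injury, and 46.6 ± 3.42 and 32.6 ± 0.63 after injury. Adam8, a membrane metalloproteinase, was 5.25 ± 1.03 under vehicle and 8.66 ± 0.60 under IPA without injury, and 87.9 ± 10.8 and 82.1 ± 5.01 after injury. DESeq2, a tool chosen after seeing the data, called these 3 genes in the interaction.

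Groups did not overlap for 25.2% of genes when IPA and vehicle were compared without injury and for 11.4% after injury. For a single gene, chance gives 10% for 3 libraries against 3. Genes of a library share trends, so the share over all genes can vary widely between groupings. It was not computed for other groupings, so 25.2% is not shown to exceed chance.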
